A study of Mus musculus with 6 samples.

How the data were processed

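RNA was sequenced from mouse mesenchymal stromal cells of the Prx1 lineage. Per the labels' protocols, femurs and tibias were cut into chips and digested with collagenase, the chips were cultured, and cells carrying the fluorescent Cre reporter were isolated by sorting. All mice carried Prx1-Cre, which is active in limb mesenchyme, and a YFP reporter. WT mice had unaltered Zeb1 alleles, and mice named Zeb1Prx1 carried Zeb1 alleles that Cre recombines. Each genotype had 3 libraries. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

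The deposited table gives 54532 genes with FPKM (fragments normalised to gene length and library total) in each library, as the authors computed them, beside gene names, coordinates and lengths per the file headers. The genome build was mm10, per the submitters' processing notes, and 54495 of the gene identifiers occur in GENCODE release M21, with identical coordinates for 98.3% of them. The aligner, the counting tool and its use of strand are not given in the sources used here. Fragments from overlapping or antisense genes therefore cannot be told apart, and genes with close copies, such as Y-linked genes with X-linked partners, Bglap and Bglap2, or Hspa1b, are uncertain to that extent.

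FPKM multiplied by the deposited gene length was a whole multiple of 1 step per library for 127408 of 127408 non-zero values, within a relative tolerance of 1e-06. Fragment numbers recovered in this way summed to between 14724357 and 18354894 per library. The total implied by the step was 0.973 to 1.04 times that sum, so the deposited FPKM may carry a scaling factor for each library besides the total. A count of 3 fragments, the upper limit a count of 0 allows, equals 0.163 to 0.204 CPM of the assigned fragments. Limits and 95% intervals from fragments cover counting error only.

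The main test, fixed before the data were examined, was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1) with an intensity trend, comparing Zeb1Prx1 with WT without a block, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Genes needed an FPKM of at least 1 in at least 3 of the 6 libraries, which left 12534. Fold changes on this scale understate the change of low genes; folds of mean FPKM are given beside them. Before the data were examined, 27 gene lists were also fixed. The 21 lists with at least 5 tested members were compared with all other genes by camera at a preset correlation of 0.01 and adjusted over the lists. P-values of single members were also adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives.

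Genes were named by a fixed rule. Zeb1, the targeted gene, and Fgfr3, which the series title names, were always named. Protein-coding genes past the threshold, with a mean of at least 5 FPKM in the higher genotype and no overlap between genotypes, came next. Because fewer than 5 genes passed, the fallback of the rule applied, which took the 6 with the smallest unadjusted p in each direction, given as not passing. Up to 4 members of each list with the smallest adjusted p completed the rule.

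The test was checked on data simulated from the means of these 12534 genes in these libraries, with 50 genes changed at each fold. With each gene's own dispersion, it called 2% of genes changed 1.5-fold, 30% at 2-fold, 70% at 4-fold and 84% at 8-fold, and 0.073% of unchanged genes. With the median dispersion for every gene, these shares were 10%, 58%, 100% and 100%, and 0.13% of unchanged genes. The simulated genes varied independently of each other, without the structure that genes of the measured libraries share. These shares may therefore not hold for the measured libraries. The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, libraries rescaled to an equal FPKM sum, median-of-ratios and quantile scaling, the replicate number as a block, no intensity trend, library weights, protein-coding genes alone, voom on the recovered fragments, and leaving out each library. Chosen after seeing the data were the mean of the macrophage list or of the skeletal stromal list as a covariate, and leaving out genes of chromosomes X and Y.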

Results

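Transcriptomes of sorted Prx1-lineage stromal cells from compact bone were compared between WT mice and Zeb1Prx1 mice, in which Zeb1 is deleted by Prx1-Cre, with 3 libraries per genotype and 14724357 to 18354894 assigned fragments per library. The comparison addresses how Zeb1, a zinc-finger repressor best known from epithelial-mesenchymal transition, acts in chondrocyte and osteoblast differentiation and how it relates to Fgfr3, the FGF receptor that restrains growth of cartilage. Values are FPKM as mean ± SD with n = 3 per genotype, and log2 changes are Zeb1Prx1 minus WT on log2(FPKM + 1) with the standard error (SE).

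Zeb1 was measured first, since it checks the labels. Zeb1 (ENSMUSG00000024238, mm10 chromosome 18, 5591860 to 5775467) had 8.0 ± 1.98 FPKM in WT and 2.12 ± 0.646 in Zeb1Prx1 libraries, a log2 change of -1.53 (SE 0.22, 95% interval -2.05 to -1.01). Each mutant library (1.92, 1.59 and 2.84) lay below each WT library (6.61, 10.3 and 7.12). Fgfr3 (ENSMUSG00000054252, chromosome 5, 33721674 to 33737068) had 0.527 ± 0.00876 FPKM in WT, from 57 to 69 fragments per library, and 3.65 ± 1.77 in Zeb1Prx1, from 315 to 622 fragments. This was 6.93-fold in mean FPKM, a log2 change of 1.54 (SE 0.26). By limma, neither passed over all genes (adjusted p = 0.229 for Zeb1 and 0.258 for Fgfr3), and adjusted over this pair alone both passed (adjusted p = 0.000439 and 0.000643). Fgfr3 was taken from the series title, which may itself rest on these data, so its p over the pair is not an independent test. With library weights, both passed over all genes (limma adjusted p = 0.042 and 0.0328).

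**Figure D1:**
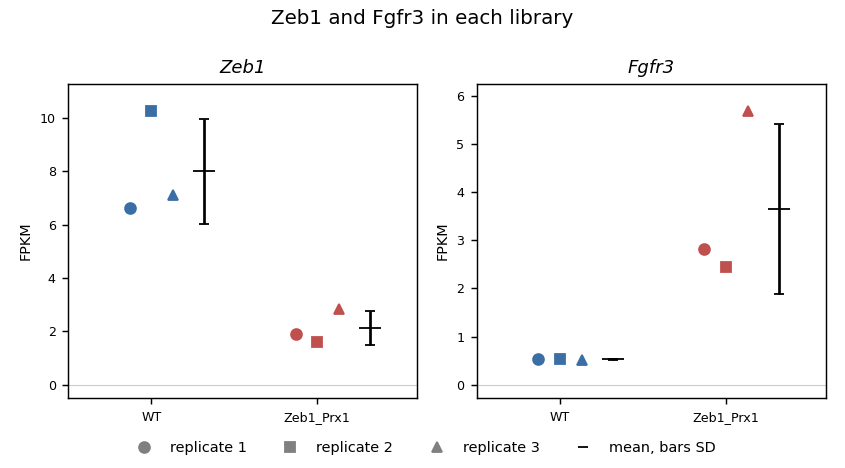
FPKM of Zeb1 (left) and Fgfr3 (right) in the 3 WT and 3 Zeb1Prx1 libraries, 1 symbol per library, with mean and SD as bars. Zeb1 lies at 1.59 to 2.84 FPKM in Zeb1Prx1 against 6.61 to 10.3 in WT, and Fgfr3 at 2.44 to 5.69 against 0.519 to 0.536.

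Across all genes, no single gene passed. Among protein-coding genes with a mean of at least 5 FPKM in the higher genotype and no overlap between genotypes, Fah, Spint2 and Tmem238 had the smallest unadjusted p on the higher side and Zeb1, Gatm and Abcb4 on the lower. Limma called 0 of 12534 genes higher and 0 lower (smallest adjusted p = 0.22), and voom on the recovered fragments also called 0. At an unadjusted p under 0.05, limma counted 1897 genes, of which 1022 were higher and 875 lower, where chance gives 627, and voom counted 1887. This count was 1118, 1135 and 1184 without WT replicate 2, WT replicate 3 and Zeb1Prx1 replicate 3, 3866 with library weights and 3366 with the macrophage list as a covariate. The genotypes did not overlap for 3054 genes (24.4%), where chance gives 10%. Library weights, which gave the most weight to Zeb1Prx1 replicate 3 (2.82) and the least to Zeb1Prx1 replicate 2 (0.226), called 268 genes higher and 179 lower. Leaving out Zeb1Prx1 replicate 2 gave 1 gene higher, Omd. With libraries rescaled to an equal FPKM sum, the median log2 change of all genes moved from 0.02 to -0.14, and the genes at an unadjusted p under 0.05 divided into 615 higher and 1235 lower.

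The 6 genes of this kind with the smallest unadjusted p in each direction did not pass (limma adjusted p between 0.22 and 0.258). Higher in each Zeb1Prx1 library than in each WT library were Spint2, a membrane inhibitor of serine proteases typical of epithelia (0.17 ± 0.0713 against 18.7 ± 14.3 FPKM, 10.4 without Zeb1Prx1 replicate 3, log2 change 3.85, SE 0.44), Fah of tyrosine breakdown (4.62 ± 0.645 against 14.7 ± 1.58) and the carbonyl reductase Cbr2 (23.8 ± 5.24 against 67.3 ± 9.09). So were the stress-induced pseudokinase Trib3 (14.7 ± 0.96 against 39.5 ± 8.36), Fkbp11 of the endoplasmic reticulum (3.18 ± 0.683 against 9.49 ± 1.76) and Tmem238 (2.85 ± 0.556 against 7.70 ± 0.711). Besides Zeb1, the lower side held Gatm of creatine synthesis (8.27 ± 1.20 against 2.93 ± 0.916), the phospholipid transporter Abcb4 (5.12 ± 0.868 against 2.36 ± 0.341). It also held Dock2, a leukocyte guanine-nucleotide exchange factor (16.5 ± 1.03 against 8.91 ± 1.76), Gas7 (17.4 ± 5.14 against 7.71 ± 0.463) and Dennd4b (11.6 ± 0.453 against 6.75 ± 1.17).

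Genes of cartilage were higher in Zeb1Prx1. Col2a1, the main collagen of cartilage, had 3.62 ± 2.18 FPKM in WT and 539 ± 573 in Zeb1Prx1 libraries (383, 60.0 and 1175), 149-fold in mean FPKM (61.2-fold without replicate 3), with a log2 change of 6.17 (SE 1.02). Col11a1, which forms fibrils with it, had 24.3 ± 4.21 and 106 ± 64.8 (70.6 without replicate 3). These 2 of 16 tested chondrocyte genes rose with p adjusted over the list alone (limma adjusted p = 0.00843 and 0.0253), while 0 passed over all genes. The proteoglycan Acan had 0.322 ± 0.506 against 48.1 ± 64.1 FPKM and Col11a2 0.382 ± 0.0819 against 18.1 ± 25.2. Without Zeb1Prx1 replicate 3 their mutant means were 11.5 and 3.62, and without WT replicate 2 the WT mean of Acan was 0.0305. As a list, 15 of the 16 members had a log2 change above 0, with a median of 1.40, and the list rose against all other genes (camera adjusted p = 0.000549; adjusted p = 0.608 with an estimated correlation). The median was 0.81 without WT replicate 1 and 0.90 without Zeb1Prx1 replicate 3. The call was also lost without Zeb1Prx1 replicate 1 (adjusted p = 0.0831), with the macrophage list as a covariate (adjusted p = 0.247) and by fry (adjusted p = 0.296). Over the 6 libraries, the median FPKM of all 31 chondrocyte genes was 0.184 to 0.565 in WT and 1.40, 0.963 and 12.6 in Zeb1Prx1 replicates 1, 2 and 3.

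Osteoblast genes were higher as well. Ibsp (bone sialoprotein) had 4.93 ± 1.58 FPKM in WT and 25.7 ± 14.9 in Zeb1Prx1, and Omd (osteomodulin) 3.93 ± 0.334 and 24.5 ± 13.2. Tnfrsf11b, which encodes the osteoclast-inhibiting decoy receptor osteoprotegerin, had 9.77 ± 6.16 and 100 ± 108 (38.6 in the mutant without replicate 3, 6.21 in WT without replicate 2), and the transcription factor Atf4 91.1 ± 2.54 and 152 ± 25.2. With Dlx5, named after its values were seen, these were the 5 of 19 tested members that rose with p adjusted over the list alone (limma adjusted p between 0.0165 and 0.0357), and 0 passed over all genes. The log2 change was above 0 for 16 members, with a median of 0.72, and the list rose (camera adjusted p = 0.000794; adjusted p = 0.608 with an estimated correlation). Without Zeb1Prx1 replicate 1 its adjusted p was 0.0831, and by fry 0.116. Beside these lists and those that follow, the macrophage list was lower in the fit, though not in Zeb1Prx1 replicate 2, and Y-linked transcripts were higher in the mutant libraries, with values given further on. Sp7 and Alpl, osteoblast genes named after their values were seen, overlapped between the genotypes (1.64 against 6.78, or 4.07 without Zeb1Prx1 replicate 1, and 20.3 against 45.2 FPKM in the mean).

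**Figure D2:**
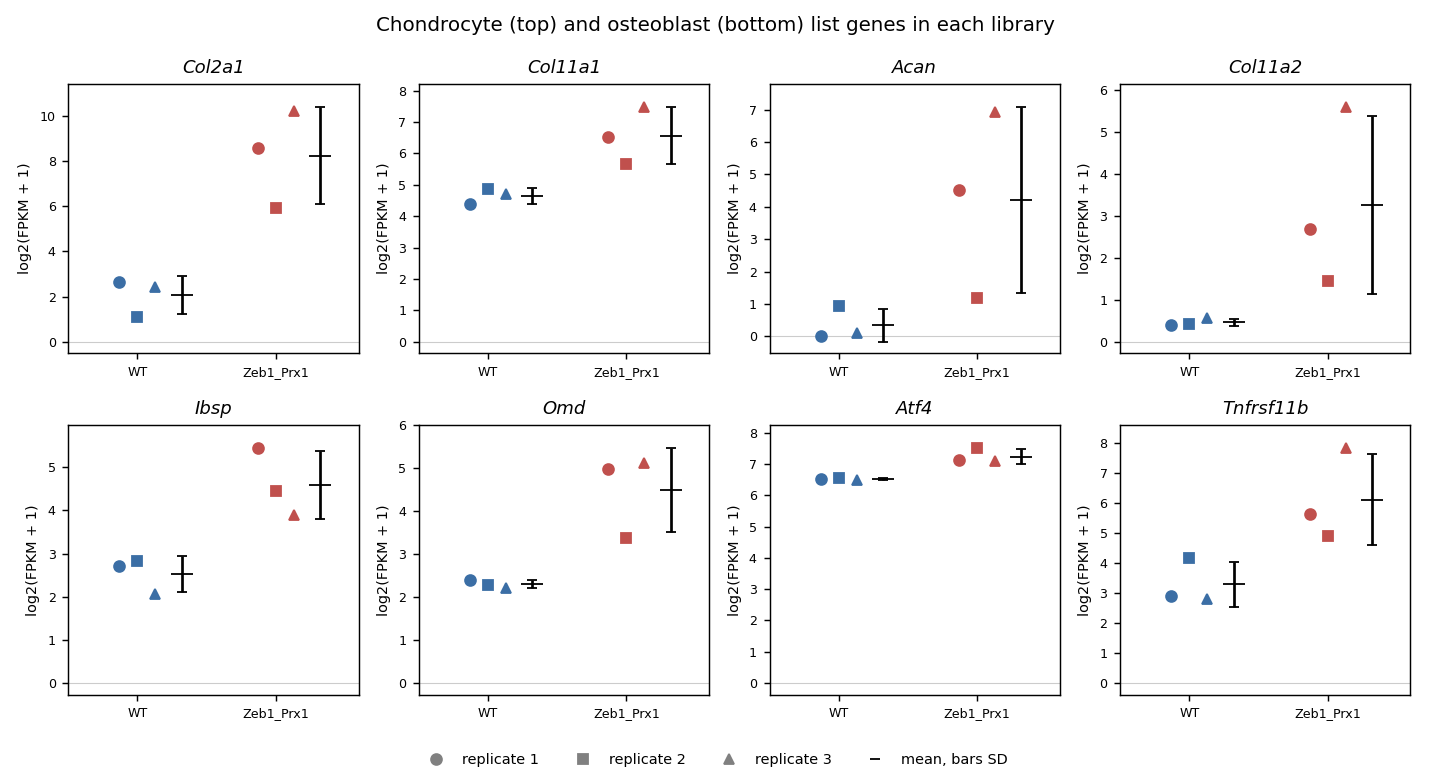
Log2(FPKM + 1) of the 4 chondrocyte genes (top) and 4 osteoblast genes (bottom) with the smallest adjusted p in their lists, 1 symbol per library, with mean and SD as bars. Col2a1 reaches 383, 60.0 and 1175 FPKM in the Zeb1Prx1 libraries, with replicate 3 highest and replicate 2 lowest.

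The list of FGF receptor signalling did not pass as a whole (camera adjusted p = 0.582, median log2 change -0.12, 16 of 24 members below 0), and Fgfr3 was its 1 member that rose with p adjusted over the list alone (limma adjusted p = 0.0154). Fgfr2 had 2.87 ± 0.718 FPKM in WT and 7.34 ± 2.81 in Zeb1Prx1, and the ligand gene Fgf7 35.1 ± 5.44 and 57.3 ± 9.67. Flrt2, a membrane protein that binds FGF receptors, had 12.1 ± 1.10 and 6.51 ± 2.28. These 3 genes did not overlap between genotypes and did not pass.

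Several epithelial genes, many of the listed ones being known targets of repression by Zeb1, were nearly silent in WT and detected in the mutant. Of the 40 listed epithelial genes, 9 reached the filter, and Spint2, F11r (a tight-junction adhesion protein, 5.58 ± 1.82 against 12.9 ± 2.64 FPKM) and Cdh3 (P-cadherin, 1.76 ± 1.16 against 5.65 ± 2.13) rose with p adjusted over the list alone (limma adjusted p = 0.000473, 0.0154 and 0.0414), with 0 past the threshold over all genes. Sema4b, another member, had 6.83 ± 1.10 against 4.65 ± 0.74 and did not pass. The list did not pass against all other genes (camera adjusted p = 0.169, median log2 change 0.25, 6 of 9 members above 0). Its median was 0.81 without WT replicate 1, 0.05 without WT replicate 3 and 0.04 without Zeb1Prx1 replicate 2. Leaving out any Zeb1Prx1 library put Spint2, under 1 FPKM in each WT library, under the filter, so the last fit tested 8 members without it. Without the filter on low values, the list passed (adjusted p = 2.16e-05), and likewise with libraries rescaled to an equal FPKM sum (adjusted p = 0.0328) and without WT replicate 1 (adjusted p = 0.033). Among the members under the filter, named here after their values were seen, the keratin Krt8 had 0 fragments in the WT libraries and 206, 23 and 454 in Zeb1Prx1, at least 217-fold higher against a limit of 3 fragments over the WT group. This limit was 106 without Zeb1Prx1 replicate 3, 137 without WT replicate 1 and 331 without Zeb1Prx1 replicate 2. The splicing factor Esrp1 had 0 against 191, 14 and 316, at least 166-fold higher (94.9, 105 and 254 without those libraries). Epcam had 0 against 26 fragments in total, at least 8.27-fold higher (5.23 without WT replicate 1), and E-cadherin (Cdh1) 10 against 73 (6.96-fold after scaling by assigned fragments, counting interval 3.58 to 15.1). Fragment totals scaled in the same way were higher in Zeb1Prx1 for 27 of the 39 members in the table. Among those that were not, also named after their values were seen, were Tjp3 (0.747-fold), Pcdh1 (0.419-fold) and the keratin Krt19 (0.546-fold). Krt19 had 683 fragments in WT, 634 of them in WT replicate 1, and 391 in Zeb1Prx1, 345 of them in replicate 2.

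Mesenchymal genes and factors of epithelial-mesenchymal transition gave no shift as a list (camera adjusted p = 0.884, 11 of 25 members above 0). The related repressor Zeb2 had 17.2 ± 0.88 FPKM in WT and 9.91 ± 2.62 in Zeb1Prx1, Twist1 20.1 ± 4.54 and 31.6 ± 7.83, and Snai2 24.7 ± 7.37 and 36.3 ± 2.94. The receptor kinase Axl had 82.4 ± 37.2 and 42.2 ± 12.8; none of the 4 passed, over the list alone included. Skeletal stem and stromal markers did not pass either (adjusted p = 0.649, 11 of 21 above 0, with a median of 0.03 and a mean of -0.02); the BMP antagonist Grem1 had 58.5 ± 33.0 against 16.3 ± 0.264. The adipocyte list did not pass (camera adjusted p = 0.213, 10 of 15 below 0), though it did with a mean FPKM of at least 5 (adjusted p = 0.042). It held lipoprotein lipase (Lpl, 51.8 ± 8.997 against 30.8 ± 5.13) and the fatty acid carrier Cd36 (13.7 ± 5.69 against 5.51 ± 2.12), which did not pass. Zeb2, Axl, Lpl and Cd36 were 0.576, 0.512, 0.595 and 0.402-fold in mean FPKM. The macrophage gene Adgre1, given further on, was 0.576-fold. Which cells in the libraries these changes lie in was not tested.

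Notch pathway genes fell as a list (camera adjusted p = 0.0319; adjusted p = 0.608 with an estimated correlation), with 10 of 12 members below 0, a median log2 change of -0.39 and 0 members called over the list alone. The receptor gene Notch1 had 3.96 ± 1.27 against 1.62 ± 0.897 FPKM, the ligand gene Jag1 8.08 ± 1.13 against 5.02 ± 1.40 and the modifier Lfng 29.5 ± 2.07 against 20.2 ± 4.58. Transcription factors of limb position and patterning rose as a list (camera adjusted p = 0.0454; adjusted p = 0.608 with an estimated correlation), with 17 of 22 members above 0, a median of 0.30 and 0 members called over the list alone. Hindlimb Pitx1 had 6.42 ± 2.47 against 25.5 ± 17.1 (15.9 without replicate 3), Hoxa9 2.38 ± 0.416 against 5.00 ± 1.19 and Tbx15 18.7 ± 1.12 against 33.4 ± 9.83. The Notch call was lost without Zeb1Prx1 replicate 1 or 3 (adjusted p = 0.0831 and 0.0718), and the limb call without WT replicate 1 or Zeb1Prx1 replicate 1 (adjusted p = 0.246 and 0.319). Both calls were also lost by fry (adjusted p = 0.155 and 0.211) and with the macrophage covariate (adjusted p = 0.247 and 0.381), Notch with a mean FPKM of at least 5 (adjusted p = 0.158), and limb with no filter, the replicate block, no trend, library weights or without X and Y genes (adjusted p between 0.0504 and 0.0936).

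The remaining signalling and state lists did not pass by camera, although 6 of them did under alternatives. The adjusted p was 0.655 for the TGF-beta and BMP pathway, 0.169 for Wnt, 0.509 for hedgehog, 0.181 for cell cycle (30 of 39 below 0), 0.953 for interferon response, 0.884 for inflammatory cytokines, 0.953 for matrix remodelling enzymes, 0.406 for glycolysis and 0.366 for immediate early and dissociation stress. The Wnt list passed upward with no filter (adjusted p = 0.0263), with libraries rescaled to an equal FPKM sum (0.0476), with library weights (0.0182) and without WT replicate 2 or Zeb1Prx1 replicate 2 (0.00932 and 0.00185). Without WT replicate 2 or Zeb1Prx1 replicate 2, the cell cycle list passed downward (adjusted p = 1.13e-10 and 0.0189), while without WT replicate 1 its median log2 change was 0.14. Glycolysis passed without WT replicate 2 (adjusted p = 0.0115), hedgehog without Zeb1Prx1 replicate 2 (0.0116), and interferon response and immediate early stress without WT replicate 3 (0.0423 and 0.0164). Id1 and Id3, targets of BMP signalling, had 15.1 ± 5.98 against 38.2 ± 9.24 and 75.5 ± 18.8 against 166 ± 54.1 FPKM and did not pass. The chemokine gene Cxcl3 (0.297 ± 0.197, or 0.194 without WT replicate 2, against 3.92 ± 1.499) was the 1 member of these 9 lists that rose with p adjusted over the list alone (limma adjusted p = 0.00629). The collagenase gene Mmp13 had 146 ± 111 (82.5 without WT replicate 2) against 384 ± 41.2, and the early gene Egr1 4.94 ± 0.061 against 2.99 ± 0.396, without passing.

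**Figure D3:**
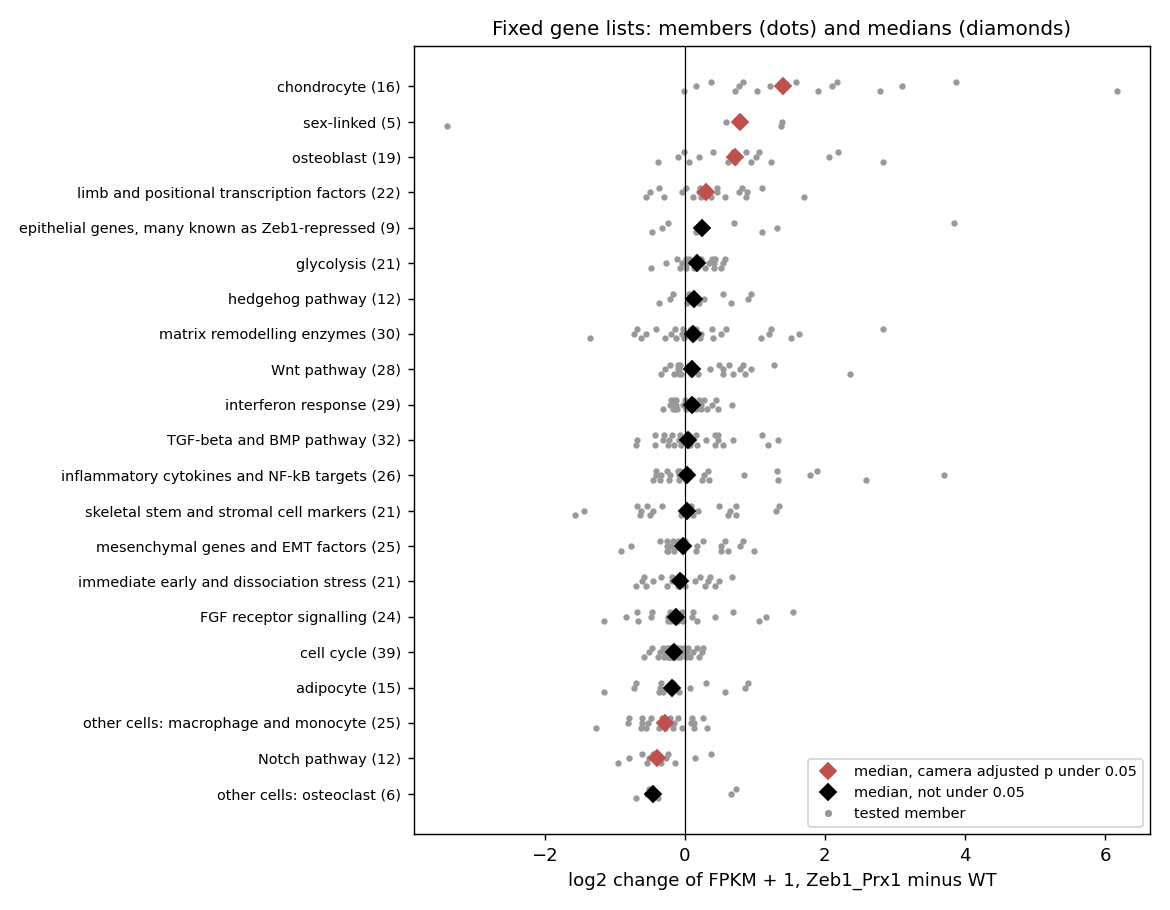
Log2 change (Zeb1Prx1 minus WT, log2 of FPKM + 1) of each tested member (dots) and the median (diamonds) of the 21 tested gene lists, with the number of tested members in brackets. Red marks the 6 lists with a camera adjusted p under the threshold, from the chondrocyte list (median 1.40) to the Notch list (median -0.39), each lost with an estimated correlation.

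Macrophage transcripts were abundant in all 6 sorted libraries and, as a list, lower in Zeb1Prx1 replicates 1 and 3 but not in replicate 2. The mean log2(FPKM + 1) of the list was 7.13, 7.20 and 7.24 in WT and 6.80, 7.32 and 6.57 in Zeb1Prx1. Replicate 2 of Zeb1Prx1 also had the highest FPKM sum (372566) and a shift toward short transcripts, given further on. Of genes named after their values were seen, Tyrobp was higher in it (558 FPKM against 267 to 306 in WT) and Csf1r lower (342 against 453 to 564). The list mean of replicate 2, which enters the macrophage covariate, may therefore not measure macrophage share alone. Lyz2, the lysozyme gene of macrophages, named after its values were seen, ranked 2 among all genes with a mean of 10197 FPKM, and the median of the 25 macrophage and monocyte genes was 120, 127 and 134 FPKM in WT and 94.0, 123 and 117 in Zeb1Prx1. Adgre1 (F4/80) had 232 ± 17.8 against 133 ± 26.4 FPKM, Cd68 382 ± 6.20 against 261 ± 12.8 and Cybb 82.0 ± 11.6 against 47.2 ± 10.6. The list fell (camera adjusted p = 0.00423; adjusted p = 0.716 with an estimated correlation), with 19 of 25 members below 0, a median log2 change of -0.28 and 0 members called over the list alone. Without Zeb1Prx1 replicate 1 or 3 the call was lost (adjusted p = 0.0953 and 0.0718, medians -0.15 and -0.14), as it was by fry (adjusted p = 0.523). Without replicate 2 the median was -0.51. The osteoclast list did not pass (adjusted p = 0.213), although with p adjusted over the list alone Tnfrsf11a, Atp6v0d2 and Itgb3 fell and Ctsk, also expressed in stromal cells, rose (34.1 ± 5.88 against 57.1 ± 8.64 FPKM; limma adjusted p between 0.016 and 0.0405 for the 4 genes). Lists of neutrophil and mast cell, lymphocyte, erythroid, endothelial, muscle and pericyte, and neural and Schwann genes had too few tested members for camera, with median FPKM over the 6 libraries between 0 and 0.138. Adjusted over those lists alone, Vwf, Eng and Mbp fell (limma adjusted p = 0.0445, 0.0445 and 0.0367).

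Sex-linked transcripts differed between the genotypes. Xist, transcribed from the inactive X chromosome, had 26.8, 40.4 and 32.9 FPKM in the WT libraries and 1.47, 0.0031 and 12.6 in the Zeb1Prx1 libraries. The Y-linked Ddx3y had 6.88 ± 2.10 against 19.2 ± 3.94, Eif2s3y 4.47 ± 1.73 against 13.4 ± 5.39 and Uty 1.24 ± 0.284 against 2.89 ± 0.561. With p adjusted over the list alone, all 5 tested members changed (limma adjusted p between 0.00543 and 0.0179), the 4 Y-linked genes upward and Xist downward, and 0 over all genes. The list passed camera upward (adjusted p = 0.0319; adjusted p = 0.608 with an estimated correlation), with a median of 0.79 and a mean of 0.15. Its call was lost by fry (adjusted p = 0.116), under the block (adjusted p = 0.0623), library weights (0.0816) and the macrophage and stromal covariates (0.347 and 0.0759).

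**Figure D4:**
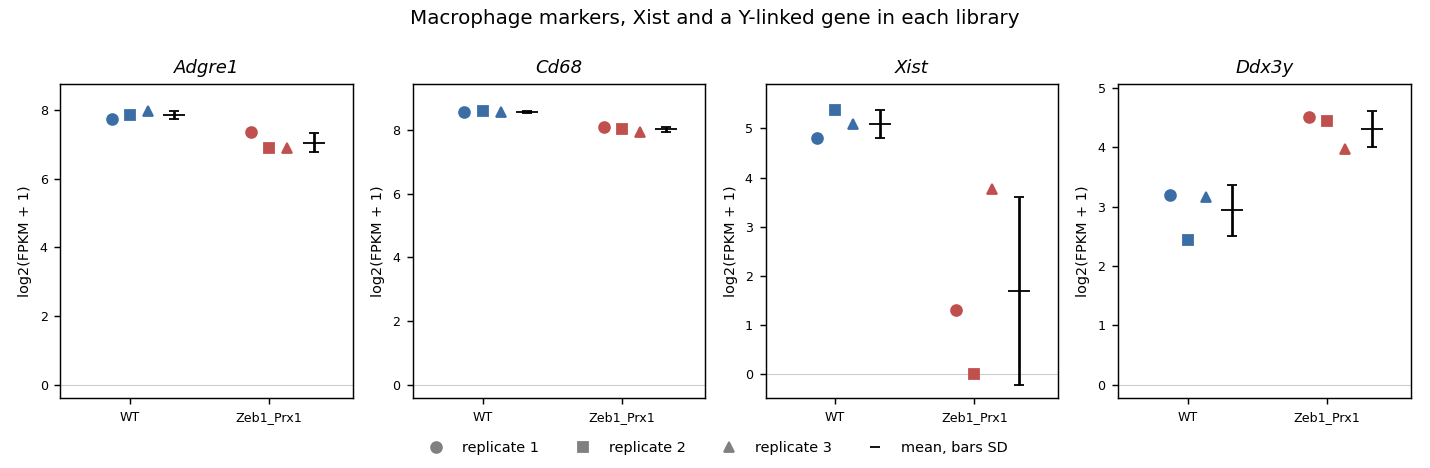
Log2(FPKM + 1) of the macrophage genes Adgre1 and Cd68, of Xist and of the Y-linked gene Ddx3y, 1 symbol per library, with mean and SD as bars. Xist is lower and Ddx3y higher in each Zeb1Prx1 library than in each WT library, and both macrophage genes are lower in each Zeb1Prx1 library, whereas the mean of the macrophage list is highest in Zeb1Prx1 replicate 2 (7.32).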

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

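Under 21 alternatives, the number of genes past the threshold stayed at 0 higher except for library weights (268), the stromal covariate, chosen after seeing the data (1, Spint2), and the fits that leave out 1 library each (0 to 1, with Omd the 1 gene without Zeb1Prx1 replicate 2). It stayed at 0 lower except for library weights (179). Zeb1 stayed lower (log2 change -1.94 to -1.34) and Fgfr3 higher (1.22 to 2.67, over 17 alternatives that tested it), and both passed with library weights alone (-1.34 and 1.93). Leaving out any Zeb1Prx1 library put Fgfr3, under 1 FPKM in each WT library, under the filter, so those fits did not test it. Its fold of mean FPKM was 5.00 to 8.08 with each Zeb1Prx1 library left out in turn. The chondrocyte list passed camera in 19 of 23 alternatives and failed with the macrophage covariate, chosen after seeing the data (adjusted p = 0.247), an estimated correlation (0.608) and fry (0.296); leaving out 1 library gave 1.62e-06 to 0.0831. The osteoblast list passed in 20 of 23 and failed with an estimated correlation (0.608) and fry (0.116); leaving out 1 library gave 1.33e-06 to 0.0831. For both lists the highest value was without Zeb1Prx1 replicate 1, with medians of 1.29 (12 chondrocyte members tested) and 0.64. Each other fit that left out 1 library passed for both lists (camera adjusted p at most 0.00785 and 0.00479). The epithelial list passed with no filter (2.16e-05), where 37 members are tested, and with libraries rescaled to an equal FPKM sum (0.0328). Leaving out 1 library gave 0.033 (without WT replicate 1) to 0.792 (without Zeb1Prx1 replicate 2, where Spint2 was not tested). The range over all 22 alternatives was 2.16e-05 to 0.792. The FGF list passed in 0 of 23, which all ask whether its genes move on balance one way. Fry for change in either direction, which does not compare a list with other genes, gave it an adjusted p of 0.0112. That form of fry also passed for the epithelial (0.00647), osteoblast (0.0112), osteoclast (0.0263), sex-linked (0.0334), Notch and immediate early lists (0.0459 each). It did not pass for the chondrocyte (0.179), macrophage (0.179) or limb list (0.25). Apart from these constructions, the cause was not tested. Of 2145 values of 105 named genes under alternatives, 42 came to pass the threshold, and 15 values of 6 genes, none called, took the other direction. Same-numbered libraries did not deviate together (correlations of residuals 0.03, -0.41 and 0.08), the highest and lowest correlations joined different numbers (0.46, WT replicate 2 with Zeb1Prx1 replicate 3, and -0.48, WT replicate 1 with Zeb1Prx1 replicate 3), and the labels do not tie a number to a litter or day. With the replicate number as a block, 0 genes were higher and 0 lower, 1347 had an unadjusted p under 0.05, and the limb and sex-linked lists lost their call (0.0623 each). Depth limits the 8 of 39 epithelial members with 0 fragments in WT.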

Other observations

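The tests on chondrocyte and osteoblast genes, on the keratins of epidermis, on epithelial fragments without the filter, on Y-linked against stromal genes and on the number of lists over splits were chosen after those results had been seen. The test on genes that escape X inactivation took the place of another after the sex-linked difference had been seen, but before the values of those genes had been. A few features of the libraries were also measured. Genes of chromosome X other than Xist (418 tested) had a median log2 change of 0.02, as did autosomal genes (0.02), and 16.0% of them had an unadjusted p under 0.05 against 15.1% of all genes. Zeb1Prx1 replicate 2 held 5.25% of its fragments in ribosomal protein genes, against 1.86 to 2.59% in the other 5 libraries, and its FPKM summed to 372566 against 278987 to 312038. Across genes, which are not independent replicates, its log2 difference from the mean of the other 5 libraries had a Spearman correlation of -0.514 with gene length, against -0.14 to 0.365 in the other libraries, a shift toward short transcripts of the size set in advance for it. This correlation was 0.202, 0.365 and 0.294 in WT replicates 1, 2 and 3, 0.215 in Zeb1Prx1 replicate 1 and -0.14 in replicate 3. The shift thus partly follows genotype. Gene length was 1327 to 4556 bases for the 6 genes named as higher by the fallback rule, and 3001 to 11425 for the 6 lower. How much of their change goes with length was not tested.

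The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.05, 1 of the 10 splits gave as many genes as the real 1897, with 869 the highest of the others, and past the adjusted threshold all 10 gave as many as the real 0, with 0 the highest other. As many lists as the real 6 passed camera in 6 of the 10 splits, with 11 the highest other, so the libraries have a structure apart from genotype that the list test at a preset correlation also calls. Among these exact splits, a camera p as small as the real one came from 4 for the chondrocyte list (real p = 2.62e-05, smallest other 9.20e-11, from a split that put Zeb1Prx1 replicate 2 with WT replicates 1 and 3). It came from 2 of the exact splits for the osteoblast list (real p = 7.56e-05, smallest other 1.81e-06) and from 3 for the epithelial list (0.0593 and 0.0106).

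Higher chondrocyte genes in the mutant might reflect fewer macrophages, a single library or genotype. On a condition given below, the tables argue against a lower macrophage share that lifts the genes of all other cells alike. The stromal and mesenchymal genes would rise with them, but their mean differed by 0.02 between libraries (SE 0.05, 95% interval -0.10 to 0.15). The chondrocyte median lay 1.43 log2 units above theirs. This holds, here and in the later uses of these lists, as far as macrophages do not express the listed genes, which was not tested. Members moved both ways, with 11 of 25 mesenchymal and 11 of 21 stromal ones above 0. Zeb2, Axl and Itgav fell (0.576, 0.512 and 0.617-fold in mean FPKM), as the macrophage gene Adgre1 did (0.576-fold). The mean of these lists may therefore hide a rise of other members. The bound on the stromal genes was set after the difference of the list means (1.77, 95% interval -0.37 to 3.92, which includes 0) had been seen. A change of cartilage genes that goes with the macrophage share stays open. With the macrophage covariate the list mean moved from 1.80 (SE 0.80) to 0.92 (SE 0.62) and the median from 1.40 to 0.77. The call was lost (camera adjusted p = 0.247), and what ended it was not tested. This covariate is highest in Zeb1Prx1 replicate 2, the library shifted toward short transcripts, so it may not measure macrophage share alone. Zeb1Prx1 replicate 3 as the sole source cannot be told apart, since without it the 12 members tested had a median of 0.90 (camera adjusted p = 0.00689) and a mean of 1.07 with an SE of 0.61. The Y-linked level follows genotype here (0 WT libraries reach the Y-linked level of any Zeb1Prx1 library), so a different sex makeup stays open. Deletion of Zeb1 and a different share of cartilage cells, both untested, and the structure seen in the splits stay open as well.

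For the epithelial genes, 0 tested members lie on chromosome X or Y. The choice of the list fixed this outcome, and it does not test an effect of sex on autosomal genes. Since 0 WT libraries reach the Y-linked level of any Zeb1Prx1 library, a different sex makeup stays open for these genes too. Little of the increase came with keratins of epidermis. The 7 keratins of the keratinocyte list increased over the WT mean by at most 0.0137 times the summed FPKM increase of the epithelial list in any Zeb1Prx1 library. Krt14 had a Zeb1Prx1 mean of 0.234 FPKM and Krt5 of 0. These keratins were chosen after their values were seen, so they give no verdict on epidermal cells. The test set in advance missed its bound of 0.1 (a keratinocyte median of 0.0483 FPKM against 0.262 for the 39 epithelial members, a ratio of 0.184). All 14 keratinocyte genes, with Sfn (5.76) and Perp (4.19), increased by 0.0984 to 0.29 times the list. Among them, Trp63 had 0.0698 to 0.225 FPKM in WT and a mean of 0.711 in Zeb1Prx1. Epidermal cells and any other source of those transcripts stay open. A lower macrophage share that lifts all other genes alike cannot be told apart for the 9 members past the filter. Their median lay 0.27 above the stromal and mesenchymal lists (permutation p = 0.3). On the condition given above for these lists, it is argued against for all 39 members, whose median log2 ratio of fragment totals lay 1.00 above. This difference was 0.83 to 1.12 with 1 library left out. Its permutation p was 1e-05, the smallest that 100000 resamples can give, with genes taken as independent. Loss of repression by Zeb1 and other epithelial cells are candidate explanations that were not tested; the sort for the Prx1-Cre reporter is meant to remove cells outside that lineage, but macrophage transcripts were abundant in all 6 libraries.

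The sex-linked difference may come from a different sex makeup of the mice behind the libraries, whose sex the labels do not give. Zeb1Prx1 replicate 2 held Xist at 0.0031 FPKM beside Ddx3y at 20.9, which goes with male cells. Each WT library held Xist (26.8 to 40.4) beside Ddx3y (4.45 to 8.19), which goes with cells of both sexes. The test on escape genes that follows did not hold without Zeb1Prx1 replicate 2, so other sources cannot be told apart by it. Genes that escape X inactivation, which are lower in male cells, had a median log2 change of -0.39, with 5 of 6 below 0, against 0.02 for 412 other X genes (permutation p = 0.0112, 1-sided, with genes taken as independent), and 0 of the 6 passed over all genes. With 1 library left out, permutation p was 0.00476 to 0.0327 in 5 fits and 0.0522 without Zeb1Prx1 replicate 2, the library shifted toward short transcripts, where 6 of 6 were below 0 with a median of -0.23. On the same condition, the stromal and mesenchymal genes argue against a lower macrophage share that lifts Y-linked genes with those of all other cells. The Y-linked median lay 1.11 above theirs, and their mean differed by 0.02 between libraries (95% interval -0.10 to 0.15). Both genotypes held Y-linked transcripts and 5 of the 6 libraries held Xist at over 1 FPKM, so mice of both sexes may be among them, and no biological explanation was tested.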
